A study of Homo sapiens with 49 samples.

How the data were processed

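RNA from Ishikawa cells was labelled and hybridized to Affymetrix HT HG-U133 Plus PM arrays, 1 array per sample, per the labels' protocols. The values used were the deposited log2 expression levels, which the submitters' processing notes tie to GCRMA and the Partek software with no version given. Background correction, normalization and summarization into probe sets were therefore the authors', and GCRMA compresses low signals toward a floor, so that changes of dim genes are uncertain. The arrays' number limits the precision.

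The table held 54715 probe sets on 49 arrays, and no column was left unused. Of these probe sets 40920 had 1 gene symbol, 864 several and 12931 none in the platform annotation. Through the Entrez identifier 40864 of the first were found in the current human gene annotation (RefSeq of GRCh38.p14, used for names only), and 0 symbols needed an update. A probe set entered if its log2 value exceeded 4 on at least 6 arrays (22721 did, and 2925 of these with no or several symbols were left out of the gene tests). The entering probe set with the highest mean over all arrays stood for its gene, which left 11075 genes. A gene whose vehicle or treated arrays all lay at or under 4 is given only a bound on its fold, taken from group means with the dim group's values set to the floor.

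Group means of all 8 groups were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8), with an intensity trend in the variance prior and Benjamini-Hochberg adjustment within each contrast (threshold 0.05). The contrasts were each concentration against vehicle and each against the next lower, plus an F test over the groups. The 29 gene lists (562 genes, 2 of them updated by synonym) were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry; the minimum of 3 measured members, which left 26 lists, was set after the numbers of measured members had been seen. Hill curves of slope 1 were fitted to the log2 levels on a grid of log10 molar EC50 from −14 to −8. An EC50 is therefore the concentration at the midpoint of the log2 change. Intervals of single genes came from the F distribution of the residual sums of squares. Intervals of medians came from 100 resamplings of arrays within groups. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

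Named genes were those past the threshold with every treated array on the same side of the vehicle mean: the 12 largest rises and the 12 largest falls at 1000 pM, the 3 largest of each at every other concentration, the 2 largest of each between consecutive concentrations, all genes of a concentration with 5 or fewer calls, ESR1, ESR2, PGR, GREB1 and ALPP in any case, and members of the lists with the called ones of largest change first. Members that did not pass are named as examples chosen after their values were seen, as are all called estrogen-responsive genes beyond the first 4.

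The calculations were tested on simulated data with the real genes' means and residual spread, noise independent between genes and arrays, and 200 changed genes per run in the contrast of 1000 pM with vehicle (11075 genes, 5 runs). Of genes changed 1.25-fold 45.6% were recovered, of those changed 1.5-fold 90%, 2-fold 98.4% and 4-fold 100%, with 5.01% of calls false. Of 100 simulated curves 92% had the true EC50 inside the interval, and of 26 simulated lists the 1 that was shifted was called and 0 others were. The real arrays deviated together across groups, as given below, so these rates may not hold for them.

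The alternatives planned with them changed the filter, the variance prior, the normalization, the weighting of arrays, the choice of probe sets, the threshold, the arrays in the fit and the replicate number as a block. Alternatives chosen after seeing the data left out 2 or 4 arrays with a high beta-actin 3′ minus 5′ difference (limits of 5 and 4 median absolute deviations, tried in that order), used that difference as a covariate, or, without those 4 arrays, blocked on 6 clusters of the other 45. Whether replicate numbers pair the arrays was judged from the correlation of deviations from the group means, per comparison, with all 6 pairs required over 0.1. They did from 1 to 3 pM (lowest 0.206), 3 to 10 pM (0.22) and 10 to 100 pM (0.271), and in no comparison with vehicle. The pairing comes from the values, since the labels name no batch. It was judged per comparison after the counts of a block over all groups had been seen, but before those of the blocks within these groups. The closing section gives their effect, and the clusters that join vehicle arrays to arrays of other groups under unlike numbers.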

Results

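The series measured how the transcriptome of Ishikawa cells, a line derived from a human endometrial adenocarcinoma, responded to ethinyl estradiol (EE), the synthetic estrogen of oral contraceptives, across a range of concentrations. Cells were kept for 72 h in medium with the ethanol vehicle (6 arrays) or with EE at 0.1 pM (6 arrays), 0.3 pM (7 arrays), 1 pM, 3 pM, 10 pM, 100 pM or 1000 pM (6 arrays each), so 49 arrays in 8 groups were compared. The arrays were alike in their distributions: the median log2 value ranged from 2.95 to 3.05 and the share of probe sets above the log2 floor of 4 ranged from 38.2% to 39.6%. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

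In 4 arrays the control probe sets for beta-actin RNA differed from the rest. In vehicle replicate 5, 0.3 pM replicate 2, 3 pM replicate 6 and 1000 pM replicate 6, the 3′ probe set exceeded the 5′ probe set by 2.67 to 4.62 (log2), against 0.80 to 2.06 in the other 45 arrays. The same difference for GAPDH was 0.40 to 1.79 in these 4 arrays and −0.21 to 0.19 in the others. The SD of their genes from the group mean was 0.286 to 0.561, against 0.104 to 0.206 in the others. All 49 arrays entered every comparison, and counts of called genes without these 4 arrays are given beside those with all. That selection was chosen after seeing the data. A limit of 5 median absolute deviations above the median actin difference was tried first and took 2 arrays (vehicle replicate 5 and 0.3 pM replicate 2), and the limit of 4 that takes these 4 arrays was set after the counts under the first limit had been seen. Counts of called genes are therefore given under both limits.

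**Figure D1:**
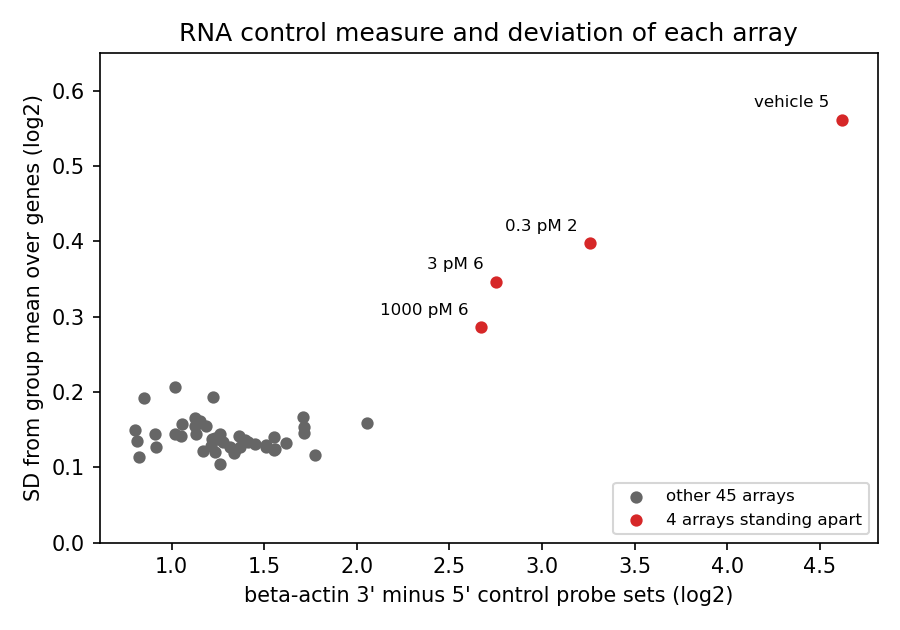
Each point is 1 of the 49 arrays: the x axis is the beta-actin 3′ minus 5′ control difference (log2) and the y axis the SD of its genes from the group mean (log2). The 4 arrays in red lie at 2.67 to 4.62 on the x axis and 0.286 to 0.561 on the y axis, apart from the other 45 arrays in grey.

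At 1000 pM, the highest concentration, the gene with the largest rise was PGR, the progesterone receptor, whose log2 level went from 4.02 ± 0.57 (SD, n = 6) in vehicle to 9.16 ± 0.19 (SD, n = 6), a 35.1-fold rise (log2 change 5.13 ± 0.21 SE, limma adjusted p = 1.26e-24). The vehicle mean lay near the floor of 4, so this fold and those of PGR below are uncertain. Its other entering probe set went from 2.05 ± 0.18 in vehicle, under the floor, to 4.86 ± 0.36 (SD). OLFM1, which encodes a secreted olfactomedin-domain glycoprotein, rose 19.7-fold (4.30 ± 0.26). GREB1, a growth regulator described in estrogen-treated breast cancer cells, rose 6.21-fold (2.63 ± 0.11), and MLPH, the vesicle transport protein melanophilin, rose 6.39-fold (2.68 ± 0.11). The calcium-activated chloride channel ANO1 rose 7.68-fold and the aminopeptidase ANPEP 8.72-fold. The vehicle mean of ANPEP (4.04) also lay near the floor, so its fold is uncertain too. SCGB2A1, a secretoglobin, rose 5.05-fold, and G0S2, an inhibitor of triglyceride lipase, rose 4.80-fold. For 4 of the named genes every vehicle array lay at or under the floor, so that only a bound can be given: the retinaldehyde reductase DHRS3 was at least 8.96-fold higher, the alkaline phosphatase ALPG at least 8.38-fold, the zinc-finger transcription factor EGR3 at least 3.08-fold and the natriuretic peptide NPPC at least 2.30-fold, each taken against the floor.

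Falls at 1000 pM were smaller. MFGE8, the secreted glycoprotein lactadherin, decreased by 1.43 on the log2 scale (SE 0.28, limma adjusted p = 2.15e-04), and the keratin KRT80 decreased by 1.41 (SE 0.16). CCN2, connective tissue growth factor, fell from 7.96 ± 0.44 to 6.70 ± 0.19 (SD, n = 6 each), a log2 change of −1.26 ± 0.18 SE. The collagen gene COL26A1 decreased by 1.28, the junction protein gene CGNL1 by 1.21, SMIM5 by 1.17, SMR3B by 1.13 and NTNG1, a netrin, by 1.00 on that scale, and POU2AF3 fell 2.15-fold. The 1000 pM means of SMIM5 (3.67), CGNL1 (3.93) and KRT80 (3.98) lay under the floor, so the size of these falls is uncertain. TAGLN, an actin-binding protein of smooth muscle, fell 1.99-fold and JUN, a subunit of the AP-1 transcription factor, fell 1.97-fold. The adhesion molecule L1CAM, under the floor on every 1000 pM array, was at least 1.55-fold lower. Without the 4 arrays, all 24 of these genes kept their direction and their call, with PGR at 5.00 ± 0.18 and MFGE8 at −1.33 ± 0.15. Each of the 24 genes lay on the same side of the vehicle mean in 6 of 6 arrays, as the rule that chose them required.

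At 1000 pM, limma called 799 of 11075 genes at an adjusted p under 0.05, of which 319 were higher and 480 lower than in vehicle. Of these, 220 changed at least 1.5-fold, 116 upward and 104 downward. Without the 4 arrays 976 genes were called (359 higher, 617 lower), and 670 genes were called in the same direction with and without them; without the 2 arrays of the stricter limit 839 were called. A fit of the vehicle and 1000 pM arrays alone called 308.

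**Figure D2:**
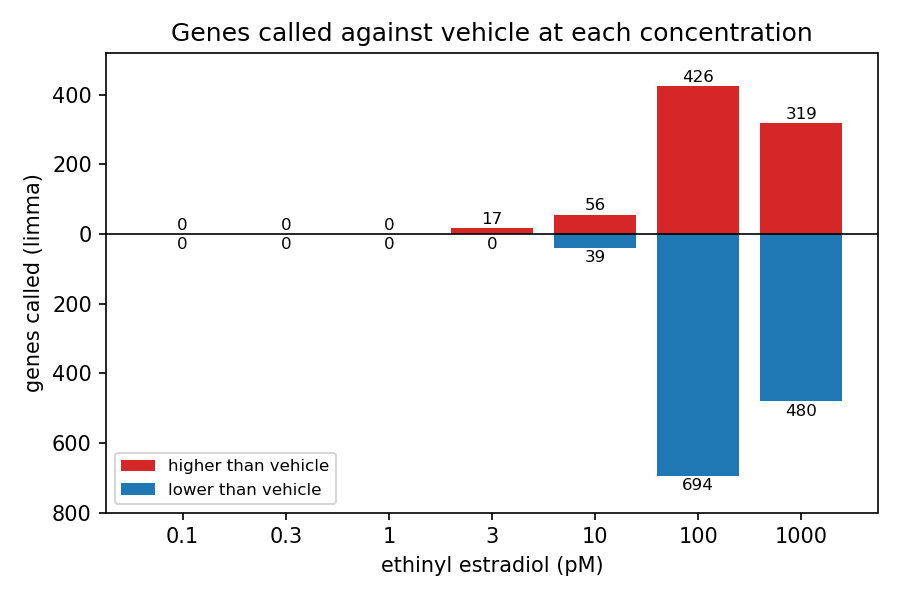
Bars give the number of genes called by limma at each EE concentration (x axis, pM) against vehicle, with higher genes above 0 and lower genes below it. No gene was called at 0.1, 0.3 or 1 pM, 17 were called at 3 pM, all higher, and the counts at 100 pM were 426 higher and 694 lower.

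The list of estrogen-responsive genes lay higher on average at 1000 pM, through some of its members. Of the 29 measured members of this list, 11 rose (PGR, OLFM1, EGR3, MLPH, GREB1, NRIP1, TGFA, CA12, SLC7A5, SIAH2 and STC2), 1 fell and 17 did not pass, and adjusted over the list alone the counts were also 11 and 1. NRIP1, a nuclear receptor corepressor, rose 3.05-fold (1.61 ± 0.11 SE), TGFA, a ligand of the EGF receptor, 2.19-fold and the carbonic anhydrase CA12 2.06-fold. SIAH2 is not called without the 4 arrays (adjusted p = 0.155 with limma), nor without vehicle replicate 5 or 1000 pM replicate 2 (highest 0.0921). AGR2, a secretory pathway disulfide isomerase that is often induced by estrogen, decreased by 0.55 on the log2 scale (SE 0.09). XBP1 (0.00 ± 0.12), RARA (0.01 ± 0.13) and MYB (−0.03 ± 0.11) did not pass, but XBP1 fell without the 4 arrays (−0.17 ± 0.05, limma adjusted p = 0.0125), which left 10 rises and 2 falls. Each called member lay on its side of the vehicle mean in 6 of 6 arrays. The list lay higher than other genes by camera (mean log2 change 0.77, adjusted p = 5.14e-15), also with an estimated correlation (adjusted p = 2.46e-06). That mean includes the large log2 changes of PGR (5.13) and OLFM1 (4.30), while 17 members did not pass.

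The list of TGF-beta and mesenchymal genes lay lower on average. Of 15 measured members 7 fell, 2 rose and 6 did not pass, with the same 7 and 2 adjusted over the list alone. The falls included CCN2, TAGLN, the smooth muscle actin ACTA2 (−0.97 ± 0.16) and CCN1, a matricellular protein (−0.84 ± 0.15). THBS1, the matrix glycoprotein thrombospondin 1, rose 2.90-fold (1.54 ± 0.11), and LTBP1, which binds latent TGF-beta, rose 1.29-fold. VIM did not pass (−0.01 ± 0.19). Camera placed the list below other genes (mean −0.29, adjusted p = 0.00276, and adjusted p = 0.00468 with an estimated correlation).

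Camera called 2 other lists at 1000 pM. Among 14 measured genes of steroid and xenobiotic metabolism 2 fell, the near-identical aldo-keto reductases AKR1C1 (−0.44 ± 0.11) and AKR1C2 (−0.42 ± 0.11), whose probe sets may read each other's RNA, and 12 did not pass; adjusted over the list alone 6 fell. The list median was −0.21 and its mean −0.24 (camera adjusted p = 0.011, and adjusted p = 0.105 with an estimated correlation). AKR1C2 is not called without vehicle replicate 5 (limma adjusted p = 0.0504). Of 3 measured ciliated epithelium markers 1 rose, the calcium-binding protein CAPS, 3.17-fold (1.66 ± 0.08), also adjusted over the list alone, while FOXJ1, a transcription factor of motile cilia, was at −0.03 ± 0.25. The median of that list was −0.03 and its mean 0.45, and camera gave an adjusted p = 0.0316 upward, and adjusted p = 0.105 with an estimated correlation. Its call was lost with the arrays numbered 2 (0.0617), 3 (0.0748) or 6 (0.231) left out of every group. The number of lists called at 1000 pM, 4 by camera, was 2 with an estimated correlation, 13 by fry, which tests a list without comparing it with other genes, and 8 by camera without replicate 1 of each group, where heat shock, MYC, NRF2 and retinoid genes were added, all upward (highest adjusted p = 0.0411). Without replicate 5 p53 targets were called downward (0.0357) and without replicate 6 NRF2 genes upward (0.0493). With an estimated correlation none of these added lists was called in the same fits (lowest camera adjusted p = 0.0599, for p53 targets).

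Other lists held genes moving in both directions at 1000 pM. Of 13 measured immediate early genes 5 fell, among them JUN, IER2 (−0.76 ± 0.12) and JUNB (−0.51 ± 0.11), and 2 rose, EGR3 and FOSL2 (2.15-fold), with the same counts adjusted over the list alone. Their median was −0.20, their mean 0.06 and the camera direction downward (adjusted p = 0.191). Of 23 growth factors, receptors and IGF-binding proteins 6 fell, including IGFBP5 (−0.79 ± 0.10) and the receptor FGFR2 (−0.69 ± 0.18), and 2 rose, TGFA and FGFR1 (0.37 ± 0.08); adjusted over the list alone 7 fell and 5 rose (camera adjusted p = 0.533). Of 15 secretory and receptive endometrium genes 3 rose, the secretoglobins SCGB2A1 and SCGB1D2 (1.12 ± 0.16) and the transcription factor SOX17 (0.72 ± 0.07), and 3 fell, among them the chaperone CLU (−0.72 ± 0.16) and the cytokine LIF (−0.46 ± 0.11). Adjusted over the list alone 5 rose and 4 fell, and the list had a median of −0.10, a mean of 0.16 and an upward camera direction (adjusted p = 0.412). Of 14 nuclear receptors and cofactors 2 rose, PGR and NRIP1, and 1 fell, FOXA1 (−0.45 ± 0.11), likewise adjusted over the list alone, with a median of −0.07, a mean of 0.38 and an upward camera direction (adjusted p = 0.298).

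Retinoid genes held 1 rise, DHRS3, and 1 fall, CYP26B1 (−0.44 ± 0.12), an enzyme that degrades retinoic acid, among 8 measured (camera adjusted p = 0.117). Of 18 p53 targets 2 fell, PLK2 (−0.86 ± 0.05) and TP53INP1 (−0.39 ± 0.07), and 1 rose, SESN1 (0.36 ± 0.09, higher in 5 of 6 arrays), which is not called without vehicle replicate 5 (limma adjusted p = 0.0564); camera gave 0.125. Of 20 hypoxia and glycolysis genes 3 rose, including the mitophagy receptor BNIP3 (0.56 ± 0.06) and the oxygen-sensing hydroxylase EGLN3, at least 1.2-fold higher against the floor (camera adjusted p = 0.0892, but called upward at 0.0298 without the 4 arrays, 0.0197 without the 2 arrays and 0.0185 without replicate 5 of each group, and in none of these fits with an estimated correlation, where it was 0.23, 0.145 and 0.164). These 3 lists gave the same counts adjusted over the list alone. Single members passed in several lists: BAG3 rose (0.57 ± 0.07) among 13 heat shock genes, LEF1 rose (0.51 ± 0.11) among 11 Wnt pathway genes, SLC7A11 rose (0.51 ± 0.13) among 12 NRF2 genes, ISG15 fell (−0.42 ± 0.10) among 10 interferon response genes, TNFAIP2 fell (−0.95 ± 0.23) among 4 NF-kB genes and KRT7 fell (−0.60 ± 0.08) among 11 epithelial markers. ASNS was called among 20 genes of the unfolded protein response (0.16 ± 0.05), but not without the 4 arrays (limma adjusted p = 0.105), nor without any of vehicle replicates 2 and 3 and 1000 pM replicates 3 and 6 (highest 0.0944). Adjusted over the list alone, these lists gave the same counts except for 2 rises among NRF2 genes, 2 falls more among Wnt genes and 1 fall more in the unfolded protein response. The camera adjusted p was 0.117 for heat shock, 0.794 for Wnt, 0.0892 for NRF2, 0.117 for interferon, 0.412 for NF-kB, 0.121 for epithelial markers and 0.626 for the unfolded protein response.

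Proliferation genes showed few calls after 72 h. Among 32 cell cycle genes CCNE2, a cyclin of S-phase entry, rose (0.30 ± 0.07), although not when its probe sets were averaged (limma adjusted p = 0.358), and 31 did not pass, among them MKI67 (0.04 ± 0.09) and CCND1 (−0.25 ± 0.14). Among 29 DNA replication genes RFC3 rose (0.35 ± 0.10), with the call lost without vehicle replicate 5 (limma adjusted p = 0.0734). The same single genes passed adjusted over the list alone. Camera gave an adjusted p of 0.739 for the cell cycle (median and mean below 0, test upward) and 0.588 for DNA replication (median below 0, mean and test above). With all arrays no member passed among 6 cyclin-dependent kinase inhibitors (camera adjusted p = 0.768), 18 cholesterol synthesis genes (0.716), 21 MYC and ribosome biogenesis genes (0.117, but called upward at 0.0247 without the 2 arrays and 0.0339 without replicate 1 of each group, and not with an estimated correlation, 0.44 and 0.379), 12 fatty acid synthesis genes (0.918; median and mean below 0, test upward) or 13 reference genes (0.794), where ACTB was at −0.12 ± 0.06 and GAPDH at 0.04 ± 0.03. Adjusted over the list alone these gave 0 calls, except 1 rise and 1 fall in fatty acid synthesis. Of 4 measured stromal markers COL1A2 rose (1.07 ± 0.14) and COL1A1 (−0.66 ± 0.15), COL3A1 and FBN1 fell, also adjusted over the list alone (camera adjusted p = 0.436); the call of COL3A1 was lost without any of vehicle replicates 2, 3 and 4 and 1000 pM replicates 4, 5 and 6 (highest limma adjusted p = 0.17), that of FBN1 without 1000 pM replicate 5 (0.0708) or without the 4 arrays (0.075). No probe set of the immune or endothelial markers entered the tests, and ALPG was the measured member of the alkaline phosphatases.

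Without the 4 arrays further list members passed at 1000 pM by limma. CDKN1A, a cyclin-dependent kinase inhibitor and p53 target, rose (0.35 ± 0.09, adjusted p = 0.00475), as did ME1, the malic enzyme of the fatty acid and NRF2 lists (0.19 ± 0.06, adjusted p = 0.022), IGF1R (0.36 ± 0.10, adjusted p = 0.00966) and SPP1 (0.52 ± 0.17, adjusted p = 0.0499). FAS (−0.42 ± 0.06), GDF15 (−0.26 ± 0.08), ITGB3 (−0.75 ± 0.09), EGFR (−0.40 ± 0.08), SMAD7 (−0.30 ± 0.10), HERPUD1 (−0.16 ± 0.04) and CDH1 (−0.13 ± 0.04) fell, the highest adjusted p being 0.043. IGFBP6, called with all arrays, was not (adjusted p = 0.0786). The counts so became 2 rises and 4 falls among p53 targets, 2 and 8 among TGF-beta genes, 3 and 6 among growth factors, 4 and 4 among secretory genes and 0 and 2 in the unfolded protein response, where XBP1 also fell. They became 0 and 2 among epithelial markers, 2 and 0 among NRF2 genes and 1 and 2 among stromal markers. Cyclin-dependent kinase inhibitors and fatty acid synthesis held 1 rise each. Apart from the estrogen-responsive genes, given above, the remaining lists kept their counts.

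The receptor through which EE is known to act, ESR1, was present at a log2 level of 8.24 ± 0.08 in vehicle and 8.29 ± 0.08 at 1000 pM (SD, n = 6 each), a difference of 0.04 ± 0.05 SE (limma adjusted p = 0.673), and was called at no concentration. Probe sets for ESR2 stayed under the floor on every array. ALPP, the placental alkaline phosphatase, also stayed under the floor, at 2.31 ± 0.22 in vehicle and 3.40 ± 0.34 at 1000 pM. ALPP and ALPG are near-identical in sequence, so the probe set assigned to ALPG may also read ALPP.

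At 100 pM the same genes led: PGR rose 28.1-fold (4.81 ± 0.21 SE), OLFM1 17.8-fold (4.16 ± 0.26) and DHRS3 at least 6.90-fold against the floor, while COL26A1 (−1.39 ± 0.28), KRT80 (−1.36 ± 0.16) and MFGE8 (−1.32 ± 0.28) fell. Among estrogen-responsive genes 11 rose and 1 fell, or 11 and 4 adjusted over the list alone (camera adjusted p = 2.35e-12, and adjusted p = 1.79e-05 with an estimated correlation). Limma called 1120 genes, 426 higher and 694 lower, of which 195 reached 1.5-fold (99 higher, 96 lower). The count without the 4 arrays was 1220 and without the 2 arrays 841. It was 710 without vehicle replicate 5 and 1790 without vehicle replicate 6, and the fit of the 2 groups alone called 290.

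At 10 pM PGR rose 7.56-fold (2.92 ± 0.21), OLFM1 7.52-fold (2.91 ± 0.26) and ALPG at least 2.71-fold against the floor. KRT80 (−0.81 ± 0.16), SMIM5 (−0.69 ± 0.13) and L1CAM (−0.86 ± 0.20) fell, L1CAM not without vehicle replicate 5 or 10 pM replicate 5 (highest limma adjusted p = 0.0831). The 10 pM mean of L1CAM, 3.77, lay under the floor. Among estrogen-responsive genes 8 rose, also adjusted over the list alone (camera adjusted p = 7.21e-09, and adjusted p = 3.34e-04 with an estimated correlation). Limma called 95 genes, 56 higher and 39 lower, 34 of them at least 1.5-fold. The majority of higher genes was not stable: without the 4 arrays 77 were higher and 77 lower (154), with array weights 81 and 79, without vehicle replicate 6 64 and 81 (145) and with arrays centred on their medians 55 and 21. The count was 94 without the 2 arrays and 33 in the fit of the 2 groups alone (27 higher, 6 lower).

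At 3 pM, the lowest concentration with a call, all 17 called genes were higher than in vehicle. OLFM1 rose 3.41-fold (1.77 ± 0.26), PGR 3.05-fold (1.61 ± 0.21, limma adjusted p = 1.49e-05) and ALPG at least 1.35-fold against the floor. TGFA (0.53 ± 0.09), THBS1 (0.58 ± 0.11), MLPH (0.54 ± 0.11), ANO1 (0.65 ± 0.13) and the mTOR inhibitor DEPTOR (0.46 ± 0.07) were also called, with DHRS3, SLCO2A1, GREB1, CILP, RHOBTB1, EPB41L2, CAPS, SLC6A6 and HES2. These genes, beyond the first 3, were named after their values were seen. With all entering probe sets fitted, THBS1 was called in 1 of 4 and PGR in 1 of 2. TGFA and EPB41L2 were called in 1 of 3 each, CAPS in 2 of 3 and OLFM1 in 2 of 2. GREB1 was called in 0 of 1. The call of GREB1 (0.51 ± 0.11) was lost without any of vehicle replicates 1, 3, 5 and 6 and 3 pM replicates 1, 3, 4 and 5 (highest limma adjusted p = 0.159). Among estrogen-responsive genes 5 rose, also adjusted over the list alone (camera adjusted p = 2.15e-04, and adjusted p = 0.0295 with an estimated correlation), the single list called, and 0 lists were called without replicate 6 of each group. Without the 4 arrays 19 genes were called, 16 of them among the 17, without the 2 arrays 17, and the fit of the 2 groups alone called 0.

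**Figure D3:**
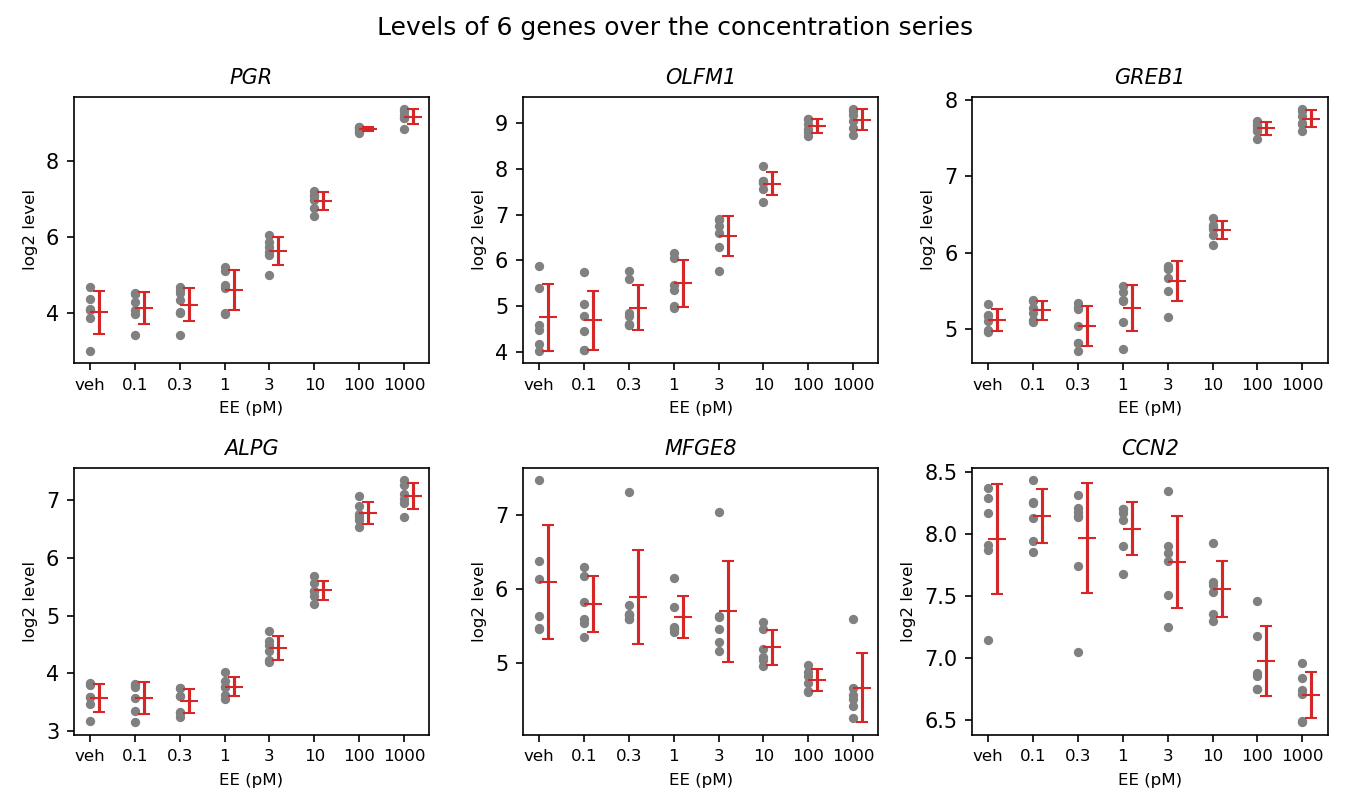
Grey points are the log2 levels of 6 genes on each array over vehicle (veh) and 7 EE concentrations (x axis, pM, equally spaced by group), and red marks the mean ± SD of each group (n = 6, or 7 at 0.3 pM). PGR goes from a mean of 4.02 in vehicle to 9.16 at 1000 pM and CCN2 from 7.96 to 6.70.

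At 0.1, 0.3 and 1 pM limma called 0 genes, with 467, 288 and 883 genes at an unadjusted p under 0.05, and the linear model without moderation also called 0 at each. PGR differed from vehicle by 0.12 ± 0.21, 0.21 ± 0.21 and 0.60 ± 0.21 SE at these concentrations (limma adjusted p = 0.820, 0.952 and 0.534), and GREB1 by 0.12 ± 0.11, −0.08 ± 0.11 and 0.15 ± 0.11. No gene list was shifted at these concentrations by camera, with an estimated correlation or by fry.

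Whether the response still moved from each concentration to the next was tested directly. From 1 to 3 pM ALPG rose, from 3.77 ± 0.17, a mean under the floor, to 4.43 ± 0.21 (SD, n = 6 each, limma adjusted p = 0.0228). It was the single gene called, and leaving out any of 1 pM replicates 3, 4 and 6 or 3 pM replicates 1, 2 and 3 ended that call (highest adjusted p = 0.174, 0 genes called). The count was 3 without 1 pM replicate 1 or without the 4 arrays, and 2 without the 2 arrays, 1 pM replicate 2 or 3 pM replicate 6. The fit of these 2 groups alone called 0 genes, and 4 with the replicate number as a block, ALPG not among them (limma adjusted p = 0.299 without the block and 0.119 with it). From 3 to 10 pM 17 genes were called, 16 higher and 1 lower. PGR rose 2.48-fold (1.31 ± 0.21) and OLFM1 2.20-fold, the latter not called without the 4 arrays (limma adjusted p = 0.121), nor without any of 3 pM replicates 2, 3, 5 and 6 and 10 pM replicates 1 to 5 (highest 0.317). JAG1, a Notch ligand, decreased by 0.23 on the log2 scale, which did not pass without any of 3 pM replicates 2, 4 and 6 and 10 pM replicates 3 and 5 (highest limma adjusted p = 0.142), nor in the 2 groups alone (0.313, and 0.0711 with the block). The count was 11 without 10 pM replicate 3, 18 without the 4 arrays and 22 without the 2 arrays. From 10 to 100 pM 109 genes were called, 83 higher and 26 lower. PGR rose 3.71-fold, and EGR3 rose from 3.30 ± 0.54 (SD, n = 6), a mean under the floor, to 5.38 ± 0.25. BLACAT1 fell from 4.53 ± 0.13 to a mean under the floor, 3.88 ± 0.20, and SMR3B fell (−0.79 ± 0.19 SE), the latter not without any of 10 pM replicates 1, 2 and 4 and 100 pM replicates 4 and 5 (highest limma adjusted p = 0.109). That count was 226 without the 4 arrays (142 higher, 84 lower) and 162 without the 2 arrays (107 and 55). The 2 groups alone gave 194 (123 and 71), and 914 with the replicate number as a block (454 higher, 460 lower). From 100 to 1000 pM limma called 0 genes (305 at an unadjusted p under 0.05, and 0 without moderation), as from 0.1 to 0.3 pM (209) and from 0.3 to 1 pM (452).

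Over the 8 groups together, limma's F test called 774 of 11075 genes. The count was 1166 without the 4 arrays and 964 without the 2 arrays.

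Half-maximal concentrations (EC50) were read from Hill curves of slope 1 fitted to log2 levels. They mark the midpoint of the log2 change, not of the change in RNA level. PGR was 7.56-fold higher at 10 pM, above its EC50, and 35.1-fold higher at 1000 pM. The 2 midpoints part more for larger changes, so genes compare on the log2 scale only. The EC50 of genes past 2-fold at 1000 pM ran from 2.09 to 105 pM. It was 3.98 pM for DEPTOR (95% interval 2.88 to 5.75), 4.37 pM for OLFM1 (3.16 to 6.03) and 7.24 pM for PGR (6.03 to 9.12). For GREB1 it was 12.6 pM (10 to 15.8) and for G0S2 14.5 pM (11 to 20). The median was 13.8 pM (12 to 15.3) over 56 genes that rose and 8.32 pM (5.36 to 14) over 10 genes that fell. Their ratio of 1.66 had an interval of 0.954 to 2.43, which includes equality. The medians include genes under the floor, such as DHRS3, ALPG, EGR3 and NPPC in vehicle and L1CAM at 1000 pM. The midpoints of such genes are uncertain, since GCRMA compresses low signals. By the reading that uses no curve, 17 of the 799 genes called at 1000 pM were called from 3 pM upward, 75 from 10 pM, 522 from 100 pM and 185 at 1000 pM alone. With the arrays of 1 number left out of every group, the count from 3 pM was 8 without replicate 4, and that from 10 pM was 42, 47 and 49 without replicates 1, 3 and 5. That from 100 pM was 337, 341 and 345 without replicates 1, 3 and 4 and 839 without replicate 6.

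The genes called at 100 and 1000 pM overlapped: 253 were higher and 361 lower at both concentrations, where independent lists would share 12.3 and 30.1, and 0 moved in opposite directions. Simulated unchanged groups against shared vehicle arrays gave at most 0. Those groups held no changed genes, so this cannot show how far shared vehicle arrays raise the overlap of changed ones. With the vehicle arrays split between the contrasts, the shared total of 614 became 281 to 337 (median 308.5 over 20 splits), and with all arrays of 1 number left out it was 393, 401 and 408 without replicates 1, 3 and 4 and 949 without replicate 6. At 10 and 1000 pM 93 genes were shared, 55 higher and 38 lower, against 1.61 and 1.69 for independent lists and 44 to 147 with split vehicle arrays, 56 without replicate 1 and 61 without replicate 3.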

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

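The tests of the 4 arrays, of their part in the counts and of shared deviations were chosen after the results were seen, and the test of a weaker response at 1000 pM was written before its result was seen. For 82 groups of 6 or 7 arrays the gap of the most distant array to the nearest other, divided by the group's range, was set against Dixon's 95% critical value, which chance passes in about 1 of 20 groups. It was passed in 20 groups, and in 14 of these the distant array was 1 of the 4 with a high beta-actin difference. For the beta-actin 3′ minus 5′ difference the ratio was 0.68 in vehicle (replicate 5), 0.752 at 0.3 pM (replicate 2) and 0.71 at 3 pM (replicate 6). For GAPDH it was 0.851 in vehicle, 0.818 at 0.3 pM, 0.898 at 3 pM and 0.83 at 1000 pM, in the same replicates and 1000 pM replicate 6, and 0.676 at 0.1 pM (replicate 1, at 0.05). For the SD from the group mean it was 0.87 in vehicle, 0.923 at 0.3 pM, 0.859 at 3 pM and 0.732 at 1000 pM in these arrays, 0.706 at 1 pM (replicate 6) and 0.645 at 100 pM (replicate 5). The share of probe sets above the floor set 1000 pM replicate 4 apart (ratio 0.713, 38.55%).

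Among named genes at 1000 pM, ANPEP was at 8.03 in replicate 6 and 6.86 to 7.16 in the others (ratio 0.742). MFGE8 was at 5.58 in replicate 6 and 4.25 to 4.66 in the others (ratio 0.691). ANO1 was at 8.05 in replicate 2 and 7.72 to 7.84 in the others (ratio 0.633), and SMR3B at 6.74 in replicate 5 and 7.27 to 7.50 in the others (ratio 0.69). ESR1 in vehicle was at 8.10 in replicate 5 and 8.25 to 8.32 in the others (ratio 0.688). Among 2925 probe sets with no or several gene symbols, which no comparison above uses, limma called 114 at 1000 pM, 53 higher and 61 lower.

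The 4 arrays stood apart in their genes as well as in the actin control. EE concentration as the source is argued against by the design, since arrays of a group share 1 concentration and 1 of the 4 was a vehicle array. The other arrays of the same 4 groups had a median SD from the group mean 1.1 times that of the arrays of the other 4 groups. Their group means include the 4 arrays, so this ratio is no separate evidence. Loss of 5′ sequence from the RNA or its cDNA may have contributed: in the GAPDH control, which did not select them, 4 of the 4 lay above every other array. Less sample RNA at the start of labelling stays open, since 3 of the 4 lay above every other array in the poly-A spikes.

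Fewer genes were called at 1000 pM (799) than at 100 pM (1120), although no gene was called between these concentrations. A weaker response is argued against only for the 95 genes called at 10 pM. Their log2 change at 1000 pM was 1.07 times that at 100 pM (median, 95% interval 1.04 to 1.11). Of these, 93 were also called at 1000 pM. They cannot show whether genes called at 100 pM but not at 1000 pM responded less, so for those genes the question stays open. The 4 arrays may have a part in the lower count, but the counts leave this undecided. The ratio of the counts was 1.40 with all arrays, 1.25 without the 4 arrays and 1.00 without the 2 arrays of the stricter limit.

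Arrays of different concentrations deviated together from their group means, although the labels give no batch. Over 885 pairs of arrays from different groups (45 arrays, without the 4), the shared deviation ran with closeness in the poly-A spikes (rank correlation −0.328) and in the beta-actin difference (−0.335), each with a permutation p of 0.001, the smallest that 1000 permutations can give. Both are consistent with runs of sample handling shared by arrays of different groups and with 5′ loss, which these tests do not separate. The comparisons with vehicle and the random splits treat the arrays as independent, so their p-values and the exclusion of chance hold only as far as that does. No biological explanation was tested.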

How the results depend on the processing

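Leaving out 2 or 4 arrays, the actin covariate, the block of 6 array clusters and the blocks within 1 to 100 pM were chosen after the results were seen, and the other alternatives were planned. Of 1881 comparisons over 118 results of named genes, 1776 kept their direction and side of the threshold, 85 lost the call and 20 changed sign. No gene was called at 0.1, 0.3 or 1 pM, nor from 0.1 to 0.3 or 0.3 to 1 pM, under any alternative run, and from 100 to 1000 pM only under the cluster block without the 4 arrays (7). That block was run only without the 4 arrays, whose own counts were 19, 154, 1220 and 976 from 3 pM upward, and was made from the tested values, so that its higher counts may be partly built in: 33 at 3 pM, 429 at 10 pM (134 higher, 295 lower), 1843 at 100 pM, 1536 at 1000 pM, 11 from 1 to 3 pM, 61 from 3 to 10 pM (35 higher, 26 lower), 497 from 10 to 100 pM (255 higher, 242 lower) and 1855 by the F test. Fits of the compared groups alone, with fewer arrays, called 0, 33, 290 and 308 genes at 3, 10, 100 and 1000 pM and 0, 11 and 194 between consecutive concentrations from 1 pM. The minimum of 1.5-fold gave 6, 34, 195 and 220 from 3 pM upward, and a threshold of 0.01 gave 59, 482 and 485 from 10 pM. For the following the cause was not tested. Array weights gave 160 genes at 10 pM, 7 from 1 to 3 pM, 307 from 10 to 100 pM and 1516 by the F test. Without the 4 arrays the counts were 154 at 10 pM, 3 from 1 to 3 pM, 226 from 10 to 100 pM and 1166 by the F test, and without the 2 arrays 2 from 1 to 3 pM. The actin covariate gave 3, 28 and 201 genes between consecutive concentrations from 1 pM and 1321 by the F test.

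With single arrays or replicate numbers left out, the counts ranged from 14 to 18 at 3 pM, 69 to 145 at 10 pM, 710 to 1790 at 100 pM, 654 to 942 at 1000 pM, 0 to 3 from 1 to 3 pM, 11 to 17 from 3 to 10 pM, 83 to 102 from 10 to 100 pM and 519 to 782 by the F test. The lists called ranged from 0 to 3 at 3 pM, 1 to 3 at 10 pM, 1 to 6 at 100 pM and 3 to 8 at 1000 pM. Genes first called ranged from 8 to 15 at 3 pM, 42 to 97 at 10 pM, 337 to 839 at 100 pM and 144 to 233 at 1000 pM, shared genes from 393 to 949 (100 and 1000 pM) and 56 to 112 (10 and 1000 pM), and the median EC50 from 13.2 to 14.5 pM for higher and 6.03 to 11.5 pM for lower genes. The mean of the ciliated markers ranged from 0.324 to 0.528.

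With an estimated correlation the ciliated (mean 0.446) and steroid (mean −0.238) lists were no longer called (adjusted p = 0.105 each by camera), which left 2 lists at 1000 pM. Fry called 7, 11 and 13 lists at 10, 100 and 1000 pM. Lists called without the 2 arrays numbered 4, 4, 6 and 6 from 3 pM upward, and without the 4 arrays 2, 3, 2 and 5, of which an estimated correlation left 3 and 2 at 1000 pM. Genes past 1.5-fold had a median EC50 of 15.8 pM (higher) and 10.5 pM (lower), and lower genes 11.2 pM without the 2 arrays. At a threshold of 0.01, 43 genes were first called at 10 pM and 284 at 100 pM, and without the 4 arrays 126 at 10 pM. Shared genes became 308.5 and 59.5 with split vehicle arrays, and 148 at 10 and 1000 pM without the 4 arrays.

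Sign changes arose in values that passed no test, for causes not tested. The camera direction of fatty acid synthesis, upward with a mean of −0.0022, turned downward without replicates 1 and 6 (means −0.0468 and −0.0753, highest 0.114), and fry gave it as downward. List means became −0.0272 for cholesterol synthesis without replicate 1 (highest 0.068) and 0.0105 for reference genes without replicate 6 (lowest −0.0496). ESR1 at 0.1 pM became −0.0207 with quantile normalization, −0.0276 with array weights, −0.0236 without the 2 or the 4 arrays and as the lowest with 1 array left out (highest 0.0209), and −0.0167 with the cluster block. PGR at 0.1 pM became −0.0953 with array weights, −0.0858 without the 2 or the 4 arrays and as the lowest with 1 array left out (highest 0.259), −0.0770 with the covariate and −0.117 with the cluster block. With probe sets averaged, ESR1 was at 0.0339, −0.0962, 0.0424 and 0.00543 at 1, 3, 10 and 100 pM. With 1 array left out it ranged from −0.0456 to 0.0118 at 10 pM and from −0.0534 to 0.000685 at 100 pM, and at 1000 pM it became −0.0108 with array weights and −0.00765 without the 4 arrays.

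The replicate number as a block over all groups gave 2 genes from 1 to 3 pM and 3 lists at 100 pM, and GREB1 at 3 pM was not called under it (limma adjusted p = 0.0529). Over all groups the numbers do not pair the arrays: 100 of 168 pairs of same-numbered arrays had deviations correlated over 0.1, the lowest correlation was −0.575, and 22 of 49 arrays had their best partner under the same number. Under unlike numbers, arrays of all groups did cluster by their deviations. Vehicle replicate 2 fell with replicates 2 and 3 at 0.1 and 0.3 pM, replicate 1 at 1, 3, 10 and 100 pM and replicate 2 at 1000 pM. Vehicle replicates 3 and 4 each likewise fell with an array of every other group. These clusters were made from the tested values, and the main comparisons with vehicle do not take them into account. In the 3 steps from 1 to 100 pM, where the numbers pair the arrays, the block within these groups with all arrays gave 1, 18 and 138 genes. In the 2 groups alone it gave 4, 18 and 914. ALPG and JAG1 lost their calls in the 2 groups alone with and without the block, and these blocks within the groups changed no call of a named gene. Signal near the floor limits what the arrays show of dim genes.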

Other observations

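The split tests of single gene lists and of splits that part pairs were chosen after the counts were seen, and the genes of the next paragraph were chosen after their values were seen.

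Some genes with every group mean above the floor differed in their EC50, read on the log2 scale. Their fitted log2 changes differed too: 1.13 for TGFA, 1.71 for SLC6A6 and 2.36 for SCGB2A1. TGFA, read from 1 of its 3 entering probe sets, reached the midpoint of its log2 change at 3.80 pM (95% interval 2.51 to 5.75). The taurine transporter SLC6A6 did so at 14.5 pM (11.5 to 18.2) and SCGB2A1 at 22.9 pM (12.6 to 45.7), and these intervals do not overlap that of TGFA.

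Whether other splits of the samples give results as large was tested with 100 splits per result, the real split included. At 10, 100 and 1000 pM 1 split each, the real one, was as large. The real counts were 95, 1120 and 799, and the highest others 53, 576 and 623. At 3 pM 4 of 100 splits were as large (17 real), but the highest other split called 1346 genes, many times the real count. This points to a structure of the samples, as does 1501 in a split at 0.3 pM. The splits assume arrays without such a structure, so they leave chance undecided at 3 pM. Those at 10, 100 and 1000 pM draw on the same vehicle arrays, so they exclude chance only if the arrays are independent. At 0.1, 0.3 and 1 pM, where 0 genes were called, 100 of 100 splits gave as many (highest others 1, 1501 and 0). From 3 to 10 pM 1 split (17 real, 2 the highest other) and from 10 to 100 pM 1 split (109 and 43) gave as many. This too excludes chance only if the arrays are independent. From 1 to 3 pM 2 splits gave as many (1 real, 1 the highest other). All these splits leave the pairing of the arrays aside. From 1 to 100 pM same-numbered arrays of neighbouring groups deviate together, so the 32 splits that part all 6 pairs were also compared, in the 2 groups alone. With the number as a block 1 of 32 splits was as large in each step (4, 18 and 914 real, 0 the highest other), and without it 32, 1 and 1 (0, 11 and 194 real, 0 the highest other). For the step from 1 to 3 pM chance can therefore be excluded only for the blocked count of 4, which does not hold ALPG, and not for the call of ALPG. From 0.1 to 0.3, 0.3 to 1 and 100 to 1000 pM, with 0 real calls, 100 splits gave as many (highest others 1, 2 and 1). For the F test 2 splits gave as many (774 real, 967 the highest other), and for the genes shared by 100 and 1000 pM (614 and 0) and by 10 and 1000 pM (93 and 5) 1 split each.

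The number of gene lists called by camera was not beyond chance at any concentration. As many were called in 38 of 100 splits at 3 pM (1 real, 5 the highest other), 51 at 10 pM (1 and 4), 49 at 100 pM (1 and 5) and 11 at 1000 pM (4 and 9). Single lists at 1000 pM were compared by the negative log10 of the camera p. Only the real split was as large for the estrogen-responsive genes (15.7 real, 11.2 the highest other), the TGF-beta and mesenchymal genes (3.67 and 3.49) and the ciliated markers (2.31 and 1.38). For steroid and xenobiotic metabolism 9 splits were (2.90 and 5.45). These 4 of 26 lists were compared because camera had called them, by the same p and with no allowance for that choice. The splits of single lists therefore do not exclude chance. The ciliated list has 3 genes and rests on CAPS. Its call was lost with an estimated correlation (camera adjusted p = 0.105) and without the arrays numbered 2, 3 or 6.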
